A study of Homo sapiens with 10 samples.

How the data were processed

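The series used chromatin immunoprecipitation with sequencing (ChIP-seq) in HEK293T, a human embryonic kidney cell line that carries the SV40 large T antigen. WDR5, a WD40-repeat subunit of the COMPASS family of histone H3 lysine 4 methyltransferase complexes, was precipitated from wild-type (WT) cells and from cells in which the microprotein EMBOW had been knocked out (KO). Tagged EMBOW was precipitated on anti-FLAG beads from cells that stably expressed it, and this list is called EMBOW-F here. The labels give 10 samples, each the 1 library of its group. The material came from nuclei digested with micrococcal nuclease, per the labels' protocols. Libraries for histone H3K4me3 and for the inputs are described in the labels and were not analysed here.

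The values used were 3 lists of peak summits and 1 list of transcripts. Bowtie2 2.4.5, MACS2 2.2.7.1, deepTools 3.5.1 and the genome build hg38 are named in the submitters' processing notes, which give no role or setting for any of them. Each deposited summit list holds intervals of 1 bp with a score that has the form of the −log10 q value MACS2 writes per summit. The unit was read from the deposited values, because the lowest −log10 q in each of the 3 lists lay just above that of a q of 0.05, which is 1.30. Which input each list was called against, and whether reads were pooled, is not given in the sources used here. The WT and KO WDR5 lists belong to their own samples. The EMBOW-F list is a file of the whole series, and it was matched to the FLAG precipitation because that is the only tagged-EMBOW ChIP in the labels. The transcript list holds 18665 Ensembl transcript models that the authors picked as new WDR5 targets dependent on EMBOW. The rule behind that choice is not given in the sources used here, and 1 line whose chromosome name had lost its first letters was repaired.

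The −log10 q values are the authors' own scores per summit, and they were used only to rank, describe or filter summits within a list. Read depth is unknown, since the lists hold no counts. A longer list can come from a deeper or cleaner library, and summit numbers were not corrected for that. The precision of each share was described with an exact (Clopper-Pearson) 95% interval, and these intervals cover counting error only. There were no replicates, so no comparison has a replicate check, and no p-values were computed.

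The plan had assumed peaks with a width and a transcription start site for each gene. The lists hold summits without widths, and the gene table used (RefSeq, assembly GRCh38.p14, 20033 protein-coding genes on chromosomes 1 to 22, X and Y) gives no strand. Each summit was therefore widened by 250 bp on either side, and summits at most 500 bp apart counted as overlapping by at least 1 bp. A summit within 1 kb of either end of a gene counted as a gene-end summit. Among 1173 genes whose ends matched a transcript of the authors' list with a known strand within 100 bp, 911 5′ ends and 50 3′ ends had a KO summit, so 94.8% (95% interval 93.2 to 96.1%) of those ends were 5′ ends. In WT these were 168 and 22 ends, or 88.4% (83.0 to 92.6%). These genes come from a list that the authors chose on these samples, so the shares do not stand for all genes. WDR5 summits with a partner in the other genotype are called shared, and the others KO-only or WT-only. The genome sequence was not used here.

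Background came from 100 random placements of each list on the same chromosomes (bedtools 2.31.1), with chromosome lengths taken from the largest coordinate seen and assembly gaps left in. For gene lists, the count of members with a gene-end summit was set beside 10000 random lists of as many protein-coding genes, which describes these libraries and was not matched on expression. The ranges quoted for random lists hold the central 95%. Random lists draw single genes, so they do not carry the shared summits of neighbouring genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The overlap and gene-end steps were tested on simulated data with planted partners and recovered all of them with 0 mismatches, and bedtools and the distance code gave the same overlaps.

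The genes named were set by a rule. For shared, KO-only, WT-only and EMBOW-F summits, it took the 10 protein-coding genes with the highest-ranked gene-end summit, with 1 gene per summit and the mean of both ranks for shared summits. SCRIB, WDR5, KIF2A, KMT2A, KMT2C, RBBP5, ASH2L and DPY30 were named whatever their values, and so were the highest-ranked members of 17 gene lists. A few genes that the rule takes are not reported here. Those lists were cytosolic and mitochondrial ribosomal proteins, replication-dependent histones, HOX genes, WDR5 partners and COMPASS genes, mitosis and spindle genes, G1/S and DNA replication genes, translation factors, subunits of oxidative phosphorylation, MYC core targets, chaperones, long neuronal genes, developmental regulators, genes silent in kidney lines, core promoters of all cells, olfactory receptors and genes named ZNF. The alternatives were a 50% reciprocal overlap of the windows (summits at most 250 bp apart), a distance of 1 kb, a q of 1e-05 or less in every list, chromosomes 1 to 22 and X only, equal numbers of WDR5 summits (the 17660 highest KO summits), gene-end windows of 500 bp and 5 kb, and merging of summits under 1 kb apart. Chosen after seeing the data were the 500 bp partner distance itself, a partner distance of 5 kb (with and without the same distance for EMBOW-F), the stricter q in the counted list only, and the EMBOW-F difference among gene-end summits.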

Results

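Summit positions from ChIP-seq of WDR5 in WT and EMBOW KO HEK293T cells, and from FLAG ChIP-seq of tagged EMBOW, were compared with each other and with the ends of protein-coding genes. Each list came from 1 library, so none of the comparisons has a replicate check and each interval covers counting error only. The WT list held 17660 summits, the KO list 21055 and the EMBOW-F list 93143. The median −log10 q, as the authors' peak caller scored it, was 6.53 in the WT list, 6.28 in the KO list and 3.25 in the EMBOW-F list. A q of 1e-05 or less was reached by 61.9% of WT, 60.7% of KO and 17.1% of EMBOW-F summits. The WDR5 lists do not measure EMBOW, and the EMBOW-F list comes from cells that express the tagged protein, so none of the lists checks the knockout. Positions are given on hg38.

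The first comparison asked where WDR5 sat on chromatin with and without EMBOW. The highest-ranked WDR5 summits lay at the same genes in both genotypes, many of them genes of the protein synthesis machinery. The 10 shared genes with the highest mean rank included the ribosomal protein genes RPL35, RPL13, RPS4X and RPL10A, CCT7 (a subunit of the cytosolic chaperonin), E2F3 (a transcription factor of G1/S genes), EEF2 (translation elongation factor 2), RNPS1 (an RNA-binding protein of the splicing machinery) and CSNK1D (casein kinase 1 delta). At RPL35 on chromosome 9 the KO summit at 124861821, 136 bp inside the gene end, ranked 3 and lay 23 bp from the WT summit that ranked 1. At CCT7 on chromosome 2 the KO summit at 73234439 ranked 1, and the WT summit 7 bp away ranked 10. At RPS4X the summits of both genotypes fell on the same base. The 10 pairs lay between 0 and 23 bp apart.

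Of the KO summits, 59.6% (95% interval 58.9 to 60.3%, 12551 summits) had a WT summit within 500 bp, against 0.688% on average in random placements. Of the WT summits, 71.3% (70.6 to 72.0%, 12594 summits) had a KO partner, against 0.813% in random placements. The KO list was 1.19 times as long as the WT list (1.17 to 1.22). It held 8504 KO-only summits against 5066 WT-only summits, a difference of 3438, and the lists themselves differed in length by 3395. With both lists shortened to 17660 summits, the share with a partner was 67.1% (66.4 to 67.8%) in KO and 67.7% (67.0 to 68.4%) in WT. Because summits pair nearly one to one, the length of the lists fixes both the difference in unshared summits and the near equality of these shares. Sharing followed rank in both lists. Among the 10% of KO summits with the highest −log10 q, 95.5% (94.6 to 96.4%) had a WT partner, and among the lowest 10% only 18.6% (16.9 to 20.3%) had one. The matching WT shares were 95.7% (94.6 to 96.6%) and 37.9% (35.6 to 40.2%). The distance that counts as a partner mattered for the unshared summits, since 50.3% of KO-only and 61.1% of WT-only summits had a summit of the other genotype within 5 kb.

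**Figure D1:**
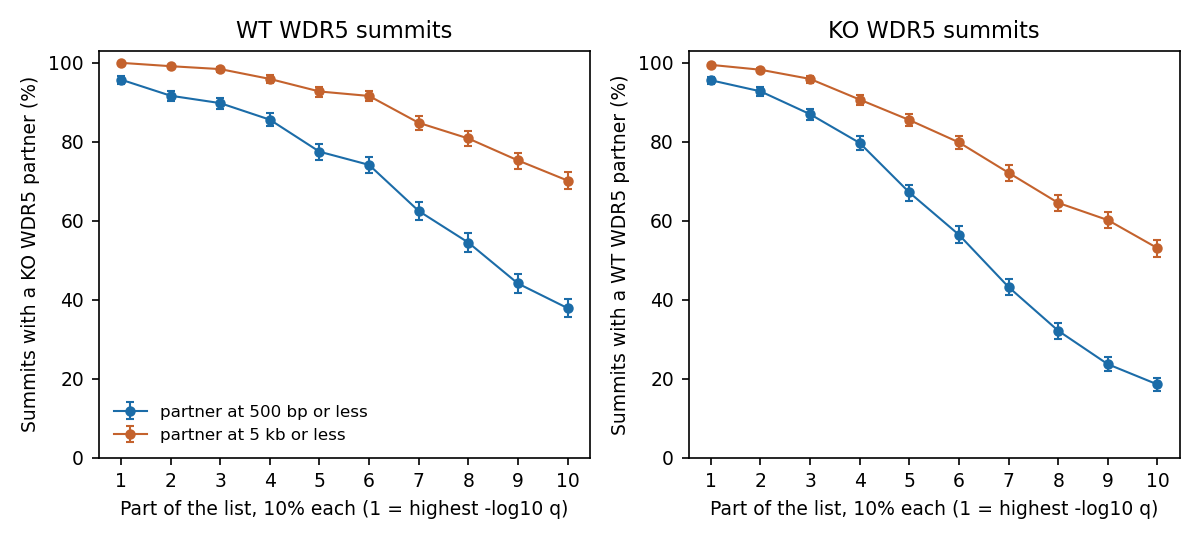
Percent of WDR5 summits with a partner in the other genotype (y axis) for 10 equal parts of each list ranked by −log10 q (x axis, 1 is highest), for WT (left) and KO (right). Points are shares at 500 bp (blue) and 5 kb (orange), bars are exact 95% intervals, and the 500 bp share goes from 95.7% to 37.9% in WT and from 95.5% to 18.6% in KO.

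WDR5 summits of both genotypes lay mostly at gene ends. A protein-coding gene end lay within 1 kb of 61.3% of WT summits (60.6 to 62.0%) and 55.8% of KO summits (55.2 to 56.5%), against 2.89% and 2.92% in random placements. Shared KO summits were at gene ends in 70.3% of cases (69.5 to 71.1%), KO-only summits in 34.4% (33.4 to 35.4%) and WT-only summits in 38.4% (37.1 to 39.8%). With lists of equal length the KO share was 61.1% (60.3 to 61.8%). By gene, 10009 of 20033 protein-coding genes had a gene-end summit in WT and 10705 in KO, and 9305 had one in both. A further 1400 genes had one in KO and none in WT, and 704 had one in WT and none in KO. Of the 2104 genes marked in a single genotype, 66.5% (64.5 to 68.6%) were marked in KO.

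The highest-ranked KO-only summits at gene ends belonged to LOC124904588, MORC2 (a chromatin-associated ATPase), EFNA5 (an ephrin ligand), NUP210 (a nuclear pore protein), HNRNPM (an RNA-binding protein), ZBTB2, USP24, PXDC1, RPL28 and AGO3 (an Argonaute protein). All 10 had a WT summit between 502 and 1335 bp away, so WDR5 was called near these genes in both genotypes at different positions. The WT-only genes were FOXC1 (a forkhead transcription factor), SLAIN1, HOXA5, ASXL3, TUG1, LOC124904588, HES6, EZH2 (the catalytic subunit of Polycomb repressive complex 2), HAPSTR1 and PHYKPL, and each had a KO summit between 516 and 2810 bp away. With 1 library per genotype, such distances do not show that WDR5 moved. MORC2 and TUG1 on chromosome 22 show how 2 summits just over 500 bp apart enter both groups under different gene names. The KO summit at 30968873 lay 99 bp outside the end of MORC2, and the WT summit at 30969398 lay 133 bp inside the end of TUG1, 525 bp from it. LOC124904588 stood in both groups, with summits 714 bp apart.

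With a partner distance of 5 kb, chosen after seeing the data, 4226 KO summits and 1969 WT summits had no partner, and other genes came to the top. In KO these were ECSIT (a mitochondrial complex I assembly factor), BBLN, TUT7 (a terminal uridylyltransferase), PLEKHH2, TMEM260, RPRM, CDKN2AIP, TPX2 (a spindle assembly factor), ZNF852 and RNASEH2A (the catalytic subunit of ribonuclease H2). The ECSIT summit (chromosome 19, 11528998) ranked 1324 in KO, with the nearest WT summit 23418 bp away. The TPX2 summit (chromosome 20, 31739437) ranked 2616 and lay 147 bp inside the gene end, 15614 bp from a WT summit. In WT they were SCUBE3, SNX15, QTMAN, SCCPDH, PAK6 (a protein kinase), GUSB (beta-glucuronidase), MTMR2 (a lipid phosphatase), RPUSD4, CCDC97 and YKT6 (a SNARE protein). The SCUBE3 summit (chromosome 6, 35214273) ranked 968 in WT, 44790 bp from a KO summit. Counted by gene, 1019 genes had a KO gene-end summit and no WT summit within 5 kb, and 420 the converse.

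Among the 8 genes to be named whatever their values, DPY30, a COMPASS subunit, carried the highest-ranked summit, at rank 122 in WT and 123 in KO. KMT2A (ranks 9351 and 3949) and KMT2C (5919 and 2880), which encode H3K4 methyltransferases, ASH2L (4175 and 4993) and WDR5 itself (3597 and 8070) had gene-end summits in both lists. So did KIF2A, a kinesin that depolymerises microtubules (1378 and 1572), and SCRIB, a cell polarity gene (4600 and 5995). RBBP5, a COMPASS subunit, had a summit in KO at rank 10570 (chromosome 1, 205121701, −log10 q 6.25), and its nearest WT summit lay 89092 bp away. These ranks come from lists of different lengths, so they do not measure a difference between genotypes. None of these 8 genes had an EMBOW-F summit within 1 kb of an end.

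Among the fixed gene lists, several of genes used by most cells had high counts, and genes silent in kidney lines had low ones. The split was not general. In WT, developmental regulators (random lists 19 to 33) and ZNF genes (232 to 277) lay within the random range, and replication-dependent histone genes lay below it. Cytosolic ribosomal protein genes had a gene-end summit in 77 of 79 cases in WT and 77 in KO, and 44 of them held a summit among the 100 highest of each list. Counts were also high, in WT and KO, for translation factors (33 and 32 of 34, including EEF2 and EEF1G), MYC core targets (34 and 35 of 36, including NCL and DDX21), G1/S and DNA replication genes (38 and 39 of 41, including E2F3 and MCM7), core promoters of all cells (40 and 39 of 43, including ACTG1) and chaperones (21 and 22 of 23, including CCT7 and CCT4). HOX genes stood at 30 and 31 of 39, including HOXB7 and HOXA6, and subunits of oxidative phosphorylation at 38 and 40 of 48, including ATP5PF and NDUFB10. Developmental regulators had 30 of 52 in each genotype, 29 of them marked in both, including SIX2 and FOXC1. Long neuronal genes had 13 and 15 of 40, including DAB1 and AGBL4. Genes silent in kidney lines had 2 and 3 of 44 (APOA1 and CD8A in both), and olfactory receptors 1 and 1 of 392. Random lists of the size of the silent list held 16 to 28 genes with a WT summit.

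Replication-dependent histone genes, which are transcribed in S phase, had a gene-end summit at 23 of 63 in WT (36.5%, 24.7 to 49.6%) and 35 in KO (55.6%, 42.5 to 68.1%). Random lists of that size held 24 to 39 in WT and 26 to 41 in KO, so the WT count was the one outside its range. Of the 14 histone genes marked in a single genotype, 13 were marked in KO, which is 92.9% (66.1 to 99.8%), at the upper edge of the 6 to 13 that random draws from all 2104 such genes gave. The 13 genes carried 11 distinct KO summits, 11 of the genes lay on chromosome 6, and 12 had no WT summit within 5 kb. H2AC16 held the highest of these summits (KO rank 4118, nearest WT summit 26437 bp away), followed by H3C10 (KO rank 7415). H2BC5 was marked in WT and not in KO, with a KO summit 1007 bp from a gene end, just outside the window. With a q of 1e-05 or less in both lists, 20 histone genes were marked in KO and not in WT. Part of that rise comes from weak WT summits that this cutoff drops. H4C1 and H2AC6, marked in both genotypes before it, had a WT −log10 q of 3.34 and KO values of 11.7 and 10.2. The converse count at that q is not given here.

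WDR5 partners and COMPASS genes had summits at 21 of 28 in WT and 26 in KO. The 5 genes added in KO were HCFC1, RBBP5, CXXC1, MCRS1 and MEN1, and none was marked in WT only. HCFC1 had a WT summit 1060 bp and MEN1 1030 bp from a gene end, just outside the window. Mitosis and spindle genes stood at 38 and 42 of 50. TPX2, AURKB and AURKA (the Aurora kinases), KIF2C, SPC25 and BUB1 were marked in KO and not in WT, though KIF2C had a WT summit 1252 bp from a gene end, and CCNB2 and PTTG1 in WT and not in KO. Mitochondrial ribosomal protein genes had 61 and 66 of 77, with 9 added in KO, such as MRPL34 and MRPL39, and 4 marked in WT and not in KO, such as MRPL11. Genes named ZNF had 267 and 286 of 510, with 54 marked in KO and not in WT, such as ZNF852, and 35 the converse, such as ZNF25. For mitosis, mitochondrial ribosomal and ZNF genes the share of single-genotype genes marked in KO fell within the range of random draws from all 2104. For COMPASS genes that range was 1 to 5, so 5 of 5 could not exceed it. The counts added in KO exceeded random draws from genes without a WT summit (COMPASS 0 to 3, mitosis 0 to 4, mitochondrial ribosomal 0 to 5, ZNF 24 to 45). The converse counts also exceeded their draws for mitochondrial ribosomal (0 to 3) and ZNF genes (10 to 25), but not for COMPASS or mitosis genes. No draw was matched on expression. At the stricter q, counts marked in KO and not in WT rose in most lists and fell in others. Developmental regulators went from 1 to 11, mitosis and spindle genes from 6 to 10 and HOX genes from 3 to 6. MYC core targets went from 1 to 5 and translation factors from 0 to 3. ZNF genes went from 54 to 50, COMPASS genes from 5 to 4 and long neuronal genes from 2 to 1. Silent genes and olfactory receptors each went from 1 to 0. A gene can enter this class at the stricter q by losing a weak WT summit, and the converse counts at that q are not given here.

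**Figure D2:**
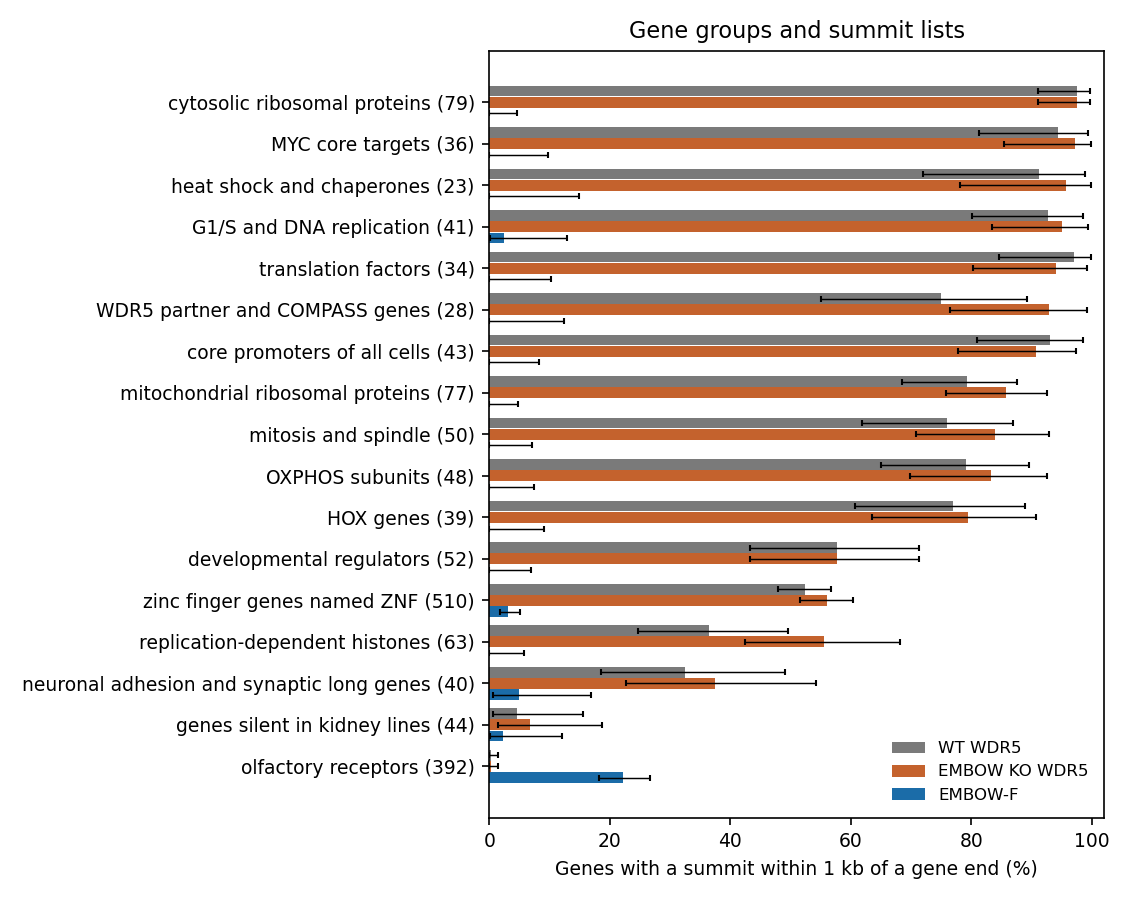
Percent of genes in each fixed list with a summit within 1 kb of a gene end (x axis), for WT WDR5 (grey), EMBOW KO WDR5 (orange) and EMBOW-F (blue), with exact 95% intervals and the number of genes in parentheses. Cytosolic ribosomal protein genes are marked by WDR5 in 77 of 79 cases in each genotype, and olfactory receptors by EMBOW-F in 87 of 392.

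The KO to WT ratio of WDR5 summit numbers differed between chromosomes. It was lowest on chromosome 7 at 1.04 (0.946 to 1.14) and highest on chromosome 20 at 1.40 (1.24 to 1.59), followed by chromosome 13 at 1.37 (1.20 to 1.56) and chromosome 3 at 1.35 (1.24 to 1.48). All 23 chromosomes compared (1 to 22 and X) had a ratio above 1, and 20 of them had an interval above 1.

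The second comparison asked whether tagged EMBOW was called at the sites of WDR5. EMBOW-F summits lay away from gene ends and far from genes. Of these summits 352, or 0.378% (0.340 to 0.419%), lay within 1 kb of a protein-coding gene end, against 2.12% in random placements. Over 100 kb from any protein-coding gene lay 71.1% of EMBOW-F summits (70.8 to 71.4%), against 32.3% in random placements, 4.64% of WT WDR5 summits and 5.34% of KO WDR5 summits. Megabases without a protein-coding gene held 33.1% of EMBOW-F summits (32.8 to 33.4%), against 12.7% in random placements. Chromosome 13 had 6779 EMBOW-F summits for 338 protein-coding genes, and chromosome 17 had 78 for 1169 genes.

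**Figure D3:**
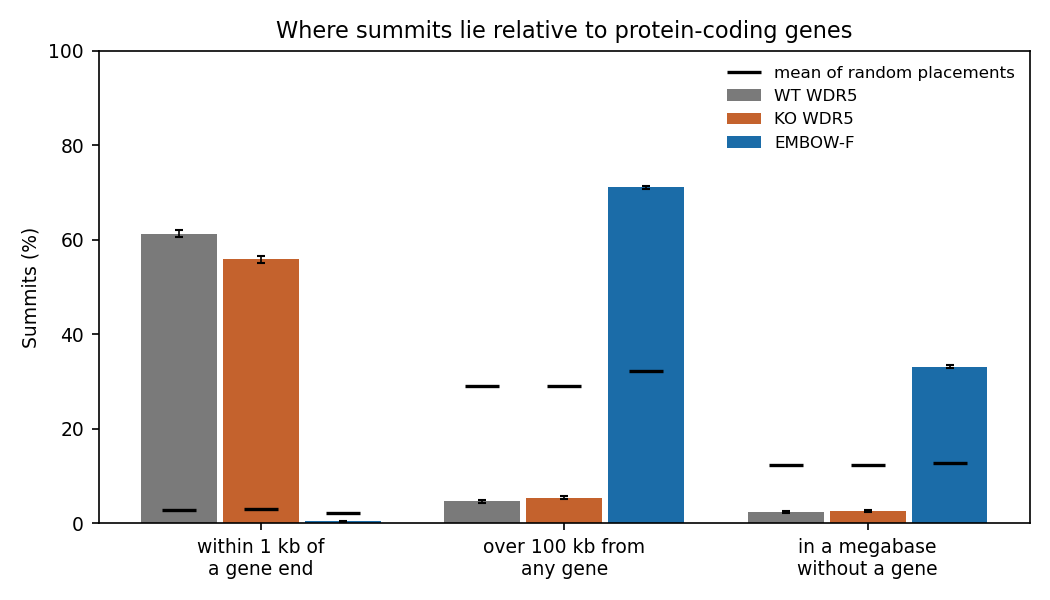
Percent of summits (y axis) within 1 kb of a protein-coding gene end, over 100 kb from any protein-coding gene and in megabases without a protein-coding gene, for WT WDR5 (grey), KO WDR5 (orange) and EMBOW-F (blue). Error bars are exact 95% intervals and black lines the mean of 100 random placements. EMBOW-F is below its line at gene ends (0.378% against 2.12%) and above it far from genes (71.1% against 32.3%).

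Of the 281 genes with an EMBOW-F gene-end summit, 87 were olfactory receptors, which are 22.2% of the 392 in the table. Random lists of that size held 2 to 10. These lists were not matched on location. The crowding of EMBOW-F summits into certain regions was therefore not separated from a preference for these genes. The 10 highest-ranked EMBOW-F genes included the olfactory receptors OR5J2, OR8H3, OR2A25, OR4A47 and OR2A2, with SCRT1 (a zinc finger repressor of neurons), MARCHF1 (a ubiquitin ligase), CFHR4 (a complement factor H related protein) and XIRP2. OR5J2 on chromosome 11 had its EMBOW-F summit at 56175911, at rank 810 with a −log10 q of 10.8, and the nearest WT WDR5 summit lay 1148961 bp away. Among the other lists, 16 ZNF genes, the long neuronal genes CTNNA2 and PTPRD, E2F2 and HBG2 had an EMBOW-F summit, and the remaining 12 lists had none.

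Over the whole lists, WDR5 and EMBOW-F summits overlapped no more often than placements made without regard to genes gave, but the highest-ranked EMBOW-F summits did. Among the 10% of EMBOW-F summits with the highest −log10 q, 2.38% (2.08 to 2.71%) lay within 500 bp of a WT WDR5 summit, against 0.498% for random placements of the whole EMBOW-F list. An EMBOW-F summit lay within 500 bp of 2.58% of WT WDR5 summits (2.35 to 2.83%) against 2.64% in random placements, and of 2.33% of KO WDR5 summits (2.13 to 2.54%) against 2.63%. Within 10 kb the shares were below the random ones, at 4.01% (3.73 to 4.31%) against 16.1% in WT and 4.07% (3.80 to 4.34%) against 16.1% in KO. The placements ignore that WDR5 summits lie mostly at gene ends and EMBOW-F summits away from them. They therefore do not test coincidence where both occur. Of the 709 WT summits within 10 kb of an EMBOW-F summit, 456 lay within 500 bp, and of 856 such KO summits 490 did. In random placements, 2.64% of WT and 2.63% of KO summits lay within 500 bp, against 16.1% within 10 kb. Close pairs thus made up a larger part of the observed neighbours, and the cause was not tested. KO-only WDR5 summits overlapped EMBOW-F summits in 4.05% of cases (3.64 to 4.49%) and shared summits in 1.16% (0.983 to 1.37%), a difference of 2.88 percentage points (2.43 to 3.36). WT-only summits did so in 6.14% (5.49 to 6.84%), so the higher overlap was found among unshared summits of both genotypes. The difference was 0.115 points (−0.0589 to 0.375) among gene-end summits and −0.105 points (−0.438 to 0.258) with a q of 1e-05 or less in every list, where the WT overlap was 1.06% and the KO overlap 0.884%.

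The third comparison set the authors' list of new WDR5 targets beside the summit lists. All 10 KO genes named at the 5 kb distance, among them ECSIT, TUT7, TPX2 and RNASEH2A, had their KO summit within 370 bp of the 5′ end of a listed transcript. Of the 10 KO-only genes named at 500 bp, MORC2, HNRNPM and PXDC1 had a listed 5′ end within 1 kb. The authors chose this list on these samples, so its overlap with KO summits is not independent evidence. Of the 18665 transcripts, 17235 lay on chromosomes 1 to 22, X and Y, and 54.9% of those (54.2 to 55.7%) overlapped a KO-only summit window. Any KO window was overlapped by 58.5% (57.8 to 59.2%), any WT window by 6.17% (5.81 to 6.54%) and any EMBOW-F window by 5.80% (5.46 to 6.16%). Merged into 2238 loci, 82.8% (81.2 to 84.3%) overlapped a KO-only window and 12.3% (10.96 to 13.7%) a WT window. Seen from the summits, 84.4% (82.2 to 86.5%) of the 1176 KO gene-end summits with no WT summit within 5 kb lay within 1 kb of a listed 5′ end, and of the 2927 KO-only gene-end summits at the 500 bp distance 42.9% (41.1 to 44.8%) did. Of the shared KO gene-end summits at 500 bp, 4.25% (3.84 to 4.69%) did. For 29.5% of the transcripts (28.8 to 30.1%) no KO summit lay within 10 kb of the 5′ end. Transcripts of one locus were counted separately there, and the interval does not allow for that. By locus, 90.0% (88.7 to 91.2%) overlapped a KO window. A 5′ end within 1 kb of a KO summit was found for 81.0% (79.3 to 82.6%) of loci. With a q of 1e-05 or less in both lists, 25.3% of transcripts overlapped a KO-only window.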

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

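The alternatives were fixed before the data were examined, except for the distance of 5 kb (for both distances or for the WDR5 partner alone), the stricter q in the counted list only and the restriction to gene-end summits, which were chosen only after the result was seen. The list of main chromosomes changed no value beyond its interval, and the KO to WT ratio of summit numbers stayed within its interval at a q of 1e-05 or less (1.17) and with summits under 1 kb apart merged (1.20). The share of KO summits with a WT partner was 50.6% at 50% reciprocal overlap, 69.5% at 1 kb, 64.5% at the stricter q, 67.1% at equal numbers, 79.9% at 5 kb and 79.2% with the stricter q in KO only. The share of WT summits with a KO partner was 60.4%, 81.8%, 75.6%, 67.7%, 88.9% and 85.1% in the same order. Overlap with EMBOW-F was 2.25% of WT and 1.90% of KO summits at 50% reciprocal overlap, 2.94% and 2.70% at 1 kb, 1.06% and 0.884% at the stricter q, and 3.65% and 3.54% at 5 kb. The EMBOW-F difference between KO-only and shared summits was 1.33 points at 50% reciprocal overlap, 4.97 at 1 kb, 2.27 at equal numbers, 10.9 at 5 kb for both the WDR5 partner and EMBOW-F, 6.50 at 5 kb for the WDR5 partner alone, 0.115 among gene-end summits and −0.105 at the stricter q, where it changed sign within an interval of −0.438 to 0.258, and the cause was not tested. The share at gene ends was 42.7% of KO, 47.2% of WT and 0.228% of EMBOW-F summits with a 500 bp window, 74.1%, 77.3% and 1.62% with 5 kb, and 68.7%, 71.2% and 0.245% at the stricter q, and it was 61.1% of KO summits at equal numbers. The share of listed transcripts that overlapped a KO-only window was 56.1% at 50% reciprocal overlap, 51.0% at 1 kb and 25.3% at the stricter q. Shares of summits with a partner or a gene end in reach rise with the distance by construction, and for the other values outside their interval, the EMBOW-F difference included, the cause was not tested. Counts of list members with a gene-end summit in KO (817) stayed within 1.5 times, at 683 to 906. Of the values for single lists, 28 stayed within 1.5 times the main count and 23 did not, most of them counts of a few genes. No paired analysis was possible because each group has 1 library and the result comes from no test. The depth of the libraries is unknown, and it limits what can be said of summit numbers.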

Other observations

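The tests of gene-distant WDR5 summits in EMBOW-F dense megabases and of neighbouring 10 Mb segments were set out before their results were seen, and all other tests here were chosen only after the result was seen.

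The densest megabases of the EMBOW-F list were nearly free of genes. The highest count, 624 EMBOW-F summits, was in the megabase of chromosome 1 from 238000001 to 239000000, which held no protein-coding gene, 9 WT and 8 KO WDR5 summits. Chromosome 13 from 83000001 to 84000000 followed with 615 EMBOW-F summits and 1 gene. The densest 5% of megabases held 43.3% of EMBOW-F summits (43.0 to 43.6%), against 10.5% in the densest 5% of each random placement's own megabases. The 2 highest-ranked EMBOW-F summits were on chromosome 1 at 125180209 and 143214705, within 6 bp of a summit in each WDR5 list.

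The first pattern is the distance of EMBOW-F summits from gene ends and their crowding into gene-poor megabases. Among the 10% of EMBOW-F summits with the highest −log10 q, only 0.193% (0.115 to 0.305%) lay at gene ends, against 2.12% in random placements. Summits just past the q cutoff therefore do not account for the distance from gene ends. Crowding was not measured for that 10%, so for the crowding this explanation stays open. A regional bias of the libraries, such as copy number or base composition, may contribute to the pattern. Of the KO WDR5 summits with no WT partner and over 10 kb from genes, 13.9% (12.3 to 15.7%) lay in the EMBOW-F densest megabases. Of the WT ones 22.9% (20.2 to 25.7%) did, against 7.67% and 7.61% for random positions that were also over 10 kb from genes. Distance beyond 10 kb was not matched. Shared summits over 10 kb from genes lay there in 2.32% of KO and 2.31% of WT cases. Copy number and base composition themselves stay open, as does binding of tagged EMBOW in these regions, which was not tested apart from them.

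The second pattern is that the highest-ranking EMBOW-F summits coincide with WDR5 summits. Of the 100 highest EMBOW-F summits, 51 lay within 500 bp of both a WT and a KO WDR5 summit. The 6 highest lay within 22 bp of a summit in each WDR5 list and at least 198353 bp from any protein-coding gene. Of the 51, 98.0% (lower bound 89.6%) were over 10 kb from any protein-coding gene, against 10.2% of all WT and 11.8% of all KO WDR5 summits. The coinciding places are thus unlike most WDR5 sites. But 83.3% of all EMBOW-F summits are that far from genes. The value of 98.0% therefore does not separate alignment hot spots present in every library from binding at the same places. Of all 147 EMBOW-F summits that coincided with both WDR5 lists, whatever their rank, 13 lay at a gene end and 87.1% over 10 kb from any protein-coding gene. Recruitment of EMBOW with WDR5 to gene ends is not the cause of the pattern among the 100 highest, because 0 of the 51 (upper bound 6.98%) lay within 1 kb of a gene end. Whether it occurs at the strongest gene-end sites of WDR5 is not settled, since 0.462% (0.150 to 1.08%, 5 of 1082) of the highest 10% of WT gene-end summits overlapped an EMBOW-F summit, against 0.133% (0.0710 to 0.228%, 13 of 9746) of the other WT gene-end summits, with overlapping intervals, and 0.490% of random positions at gene ends of the same chromosomes, olfactory receptors included. Hot spots and binding at these gene-distant places stay open, and the input libraries were not analysed here.

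The third pattern is the larger number of unpartnered summits in KO, which as a count follows from the longer list (a difference of 3438, where the lists differ in length by 3395), so what is open is why the KO list is longer, with a deeper or cleaner KO library among the untested causes. With both lists at 17660 summits, 2.96% (2.58 to 3.38%) of the top 40% in KO had no partner within 5 kb in WT, against 1.68% (1.40 to 2.01%) of the WT top 40% in the full KO list, but that list is longer and offers more partners, and against a KO list of equal length the WT share was 2.48% (2.13 to 2.87%), so summits near the q cutoff cannot be told apart from other causes, loss of EMBOW included, with 1 library each. Without the 6 chromosomes of highest ratio the KO to WT ratio was still 1.15 (1.13 to 1.18), so those 6 alone are not the whole cause. Copy number was not measured and the other chromosomes may differ in it too. The ratio therefore does not exclude chromosome-scale differences. Regional differences such as copy number may be part of the difference in length. The KO share of neighbouring 10 Mb segments correlated across segments with r = 0.418, where 1000 shufflings gave −0.13 to 0.12 in their central 95%. Neighbouring segments share a chromosome, and the KO to WT ratio differed between chromosomes. The correlation therefore does not tell differences of segments from those of whole chromosomes. Segments are not independent replicates, and a biological difference between the genotypes in such segments stays open and untested.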
